A study of Homo sapiens and Mus musculus with 6 samples.

How the data were processed

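Total RNA was extracted with RNAiso reagent and made into libraries with an NEB kit, per the labels' protocols, and how ribosomal RNA was removed is not given in the sources used here. The authors deposited 1 table of raw read counts per gene for the 4 SCP28 libraries, with gene symbols, exonic gene lengths and GO and KEGG annotation. The submitters' processing notes name cutadapt, HISAT2, HTSeq, DESeq2 and edgeR and the builds hg38 and mm39, with no versions and no roles. Start and end of IGFBP3 are the same in the deposited table and in GENCODE 29 on GRCh38. The counts are whole numbers that were not normalized, and no step after counting is recorded for them. Whether the counting used strand is not given in the sources used here, so overlapping genes cannot be separated. The exonic length is the authors' value per gene and was used only to check length trends. The table holds 61806 gene rows, 41389 with a symbol, and 99.92% of the gene identifiers matched the reference name table.

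Groups were taken from the sample titles: 2 scramble and 2 IGFBP3 knockdown libraries. The sources used here do not give the silencing sequences, how they were introduced, or whether the 2 knockdown libraries share one. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr with the group, glmQLFit and glmQLFTest, group as the only term, two-sided), and p-values were adjusted by Benjamini-Hochberg over the 16149 genes tested. A gene was called at an adjusted p under 0.05. CPM values use TMM factors. SDs are over the 2 libraries of a group. Total counts between 16252927 and 21523151 put the level of 3 counts, the upper limit that a count of 0 allows, between 0.139 and 0.185 CPM, which covers counting error only.

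Before the data were examined, 37 gene lists were fixed, covering the IGF axis, mammary basal, stem and luminal markers, signalling, metabolism, stress, metastasis signatures, other cell types and RNA quality. The 36 lists with at least 5 genes tested were compared by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists, with an estimated correlation and with fry. camera asks whether a list moves relative to other genes, and fry whether its members move, on balance, in one direction. Of 977 list entries, 976 matched a row and 853 were tested.

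Named genes followed a rule fixed before the data were examined: IGFBP3, then up to 12 rises and 12 falls among edgeR's calls with a symbol, a mean of at least 5 CPM and both knockdown libraries on the same side of both scramble libraries, then up to 4 members with the smallest p of each list described, then all tested members of the IGF axis list. As edgeR called 1 gene, the same rule was applied to the calls of DESeq2 1.42.0, a choice made after seeing the data. Genes named outside the rule were chosen after their values were seen, and some genes that the rule takes are not reported here.

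Alternatives fixed before the data were examined were DESeq2, limma-voom, RLE factors, no factors, no filter, a filter of at least 1 CPM in all 4 libraries, stricter thresholds, the replicate number as a block, and each library left out in turn, with the lone library of an arm assumed to vary like the others. Added after seeing the data were offsets for exon length and GC content (loess of each library's deviation, span 0.5), the length offset with the block, the set of genes free of the ATATTTC and TATTTCA heptamers, leave-one-out and other settings of DESeq2, and 311 KEGG and 1926 GO sets of 10 to 300 genes. GC values covered 98.2% of the tested genes.

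Heptamers were searched in the longest annotated 3′ UTR (at least 50 bases) of the protein-coding transcripts of GENCODE 29, available for 95.4% of the 10247 genes with a mean log2 CPM over 3. For each of 15662 heptamers present in at least 100 genes, the log2 ratio, limited to ±1.5, was regressed on its presence with linear and squared terms of 3′ UTR length, 3′ UTR GC content and exon length as covariates, and z is the effect over its standard error across genes, which are not independent. The matched background took the 200 genes nearest in 3′ UTR length and GC content for each called gene.

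The scripts were tested on simulated data. In counts simulated for this comparison over 16149 genes, edgeR recovered 10.4%, 49.3% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 false calls, and DESeq2 recovered 16.4%, 61.2% and 92.4%, with 21 false calls. A heptamer effect of −0.075 put into 20 shuffled data sets of 9779 genes had the lowest z in 20 of them.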

Results

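Gene expression was measured by RNA sequencing in SCP28 cells, a human breast cancer line descended from a single cell of the metastatic MDA-MB-231 line, with IGFBP3 knocked down or with a scramble control. IGFBP3 encodes insulin-like growth factor binding protein 3, a secreted protein that binds IGF1 and IGF2 and limits their access to the receptor IGF1R. Each group had 2 libraries. The total counts were 18507132 and 21523151 in the scramble libraries and 16374712 and 16252927 in the knockdown libraries. Between 24599 and 26356 genes had at least 1 count. The libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom of 19.8 between the scramble libraries and 24.7 between the knockdown libraries. The labels do not say whether they came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The series also names 1 library of mouse mammary stem cells and 1 of mouse luminal cells, which were not analysed here.

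The comparison asked which transcripts differ when the tumour cells carry less IGFBP3 mRNA, in a study of IGFBP3, mammary stem cell activity and the bioavailability of IGF. The IGFBP3 transcript (ENSG00000146674) is encoded on the minus strand of chromosome 7 from 45912245 to 45921874 in GRCh38. It fell 8.63-fold in the knockdown libraries, with a log2 fold change of −3.11 (SE 0.26) and an adjusted p of 0.0453 in edgeR's quasi-likelihood test. The scramble libraries held 871 and 1172 counts of IGFBP3, or 47.6 and 54.3 CPM (counts scaled to library size). The knockdown libraries held 71 and 121 counts, or 4.30 and 7.50 CPM. IGFBP3 was the only gene that passed this test among 16149 genes, of which 719 had an unadjusted p under 0.05 where chance alone gives about 807. The spread in this test holds the difference between libraries numbered 1 and 2, for which 2849 genes had an unadjusted p under 0.05 in edgeR. A planned block for the number called many more genes, as given below. The count of 719 therefore does not show that no other gene responded. limma-voom also called IGFBP3 alone, with an adjusted p of 0.0469. An offset for GC content, chosen after seeing the data, ended the call (adjusted p = 0.0792 in edgeR's test) and left the log2 fold change at −3.12.

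DESeq2's Wald test on the same counts called 39 genes, 13 higher and 26 lower in the knockdown libraries. Next to IGFBP3, the largest falls were in SORL1, a sorting receptor of the endosome, and STX2, a membrane fusion protein. SORL1 went from 21.5 ± 4.84 to 8.36 ± 0.339 CPM (mean ± SD, n = 2 in each group) and STX2 from 70.7 ± 2.76 to 31.2 ± 0.225 CPM. The TGF-beta co-receptor gene TGFBR3 (51.9 ± 4.03 to 28.6 ± 0.528 CPM) and the metalloprotease gene ADAMTS12 (63.2 ± 0.934 to 35.4 ± 0.848 CPM) fell as well. ELMOD2, FRMD3, DNAH2, SERP1, the kinase gene NEK7, DYNLT1, CST1 and CD2AP completed the 12 largest falls after IGFBP3, with DESeq2 log2 fold changes from −0.97 for ELMOD2 to −0.81 for CD2AP. CST1 has close paralogs among the cystatins that could share its reads.

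The largest rises called by DESeq2 were in TNFSF18, which encodes the ligand of the co-stimulatory receptor GITR, and NCEH1, a cholesterol ester hydrolase. TNFSF18 stood at 5.47 ± 1.45 CPM in the scramble and 18.3 ± 0.0407 CPM in the knockdown libraries, and NCEH1 at 187 ± 18.6 and 475 ± 74.6 CPM (mean ± SD, n = 2). HSD17B10, a mitochondrial dehydrogenase gene, rose from 21.6 ± 0.996 to 46.4 ± 5.48 CPM. JUND, a subunit gene of the transcription factor AP-1, rose with a DESeq2 adjusted p of 0.00119. The cytokine genes IL6, CXCL8 and CXCL1 rose too, as did H2AX, DYNLRB1, the BMP antagonist gene NOG, AKIRIN1 and RASD1. DESeq2's adjusted p ranged from 4.87e-10 for NCEH1 to 0.0484 for CXCL1, NOG and RASD1 among these 12 genes. All 39 genes had an unadjusted p under 0.05 in edgeR, where the adjusted p was 0.229 or more for each but IGFBP3. DESeq2 kept only part of the 39 calls when 1 library was left out, and without knockdown replicate 1 some of the called genes were not among the 39. Of the largest falls, SORL1, FRMD3, DYNLT1, TGFBR3, ADAMTS12 and CST1 were called in none of these fits. The same held for CXCL1, H2AX, DYNLRB1 and NOG among the rises. IGFBP3 and NCEH1 were called in each of these fits.

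**Figure D1:**
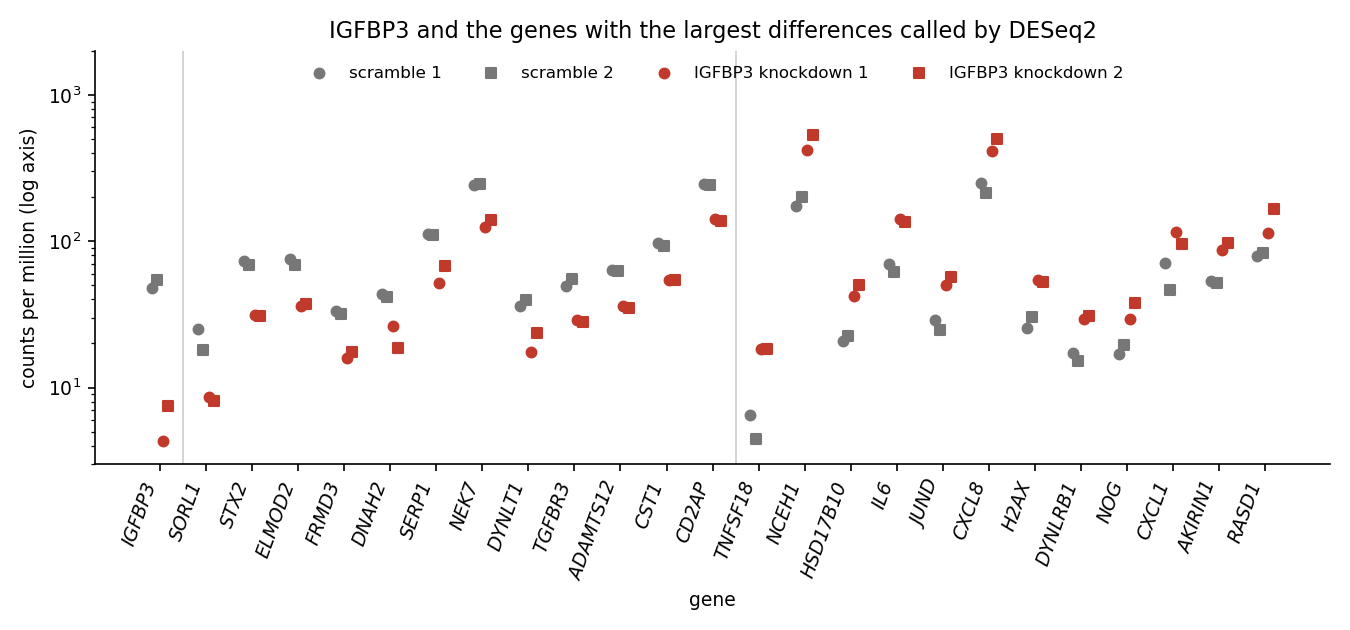
CPM on a log axis in each of the 4 libraries for IGFBP3, the 12 genes with the largest falls and the 12 with the largest rises among DESeq2's calls; grey points are scramble and red points knockdown libraries, circles replicate 1 and squares replicate 2. IGFBP3 lies at 47.6 and 54.3 CPM in the scramble libraries and at 4.30 and 7.50 CPM in the knockdown libraries.

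Of the 26 genes that DESeq2 called lower, 25 besides IGFBP3 had an annotated 3′ UTR that could be searched, and 21 of these (84.0%) held the heptamer ATATTTC or TATTTCA there. SORL1, STX2, ELMOD2, NEK7, TGFBR3, ADAMTS12 and CD2AP were among the 21, while CST1, DNAH2, ITGB4 and PRKCA had neither heptamer. The heptamers were chosen after seeing the data, from a scan of 15662 heptamers over 9779 expressed genes in which they had the lowest values. Among 9769 genes that were not called the share was 34.9%. Long 3′ UTRs hold more heptamers of any kind, and among background genes nearest in 3′ UTR length and GC content the share was 53.7%, or 13.4 of the 25 genes. The scan that chose the heptamers included the called genes, so tests of these shares are not independent evidence and their p-values are not given. With the log2 ratio adjusted for length and GC content, the 1010 genes with the 8-mer ATATTTCA had a median of −0.06. The median was −0.004 for the 1263 genes with ATATTTC but not the 8-mer. For the 4875 genes without the inner hexamer of the 8-mer it was 0.01. Between the scramble libraries the adjusted medians were 0.01 for both. IGFBP3 itself held ATATTTC at 1 place, on chromosome 7 from 45913747 to 45913753 in GRCh38, on the minus strand. This place lies in the 3′ UTR in exon 6 of 6, in the sequence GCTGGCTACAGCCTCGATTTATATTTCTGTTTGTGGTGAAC read along the transcript.

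**Figure D2:**
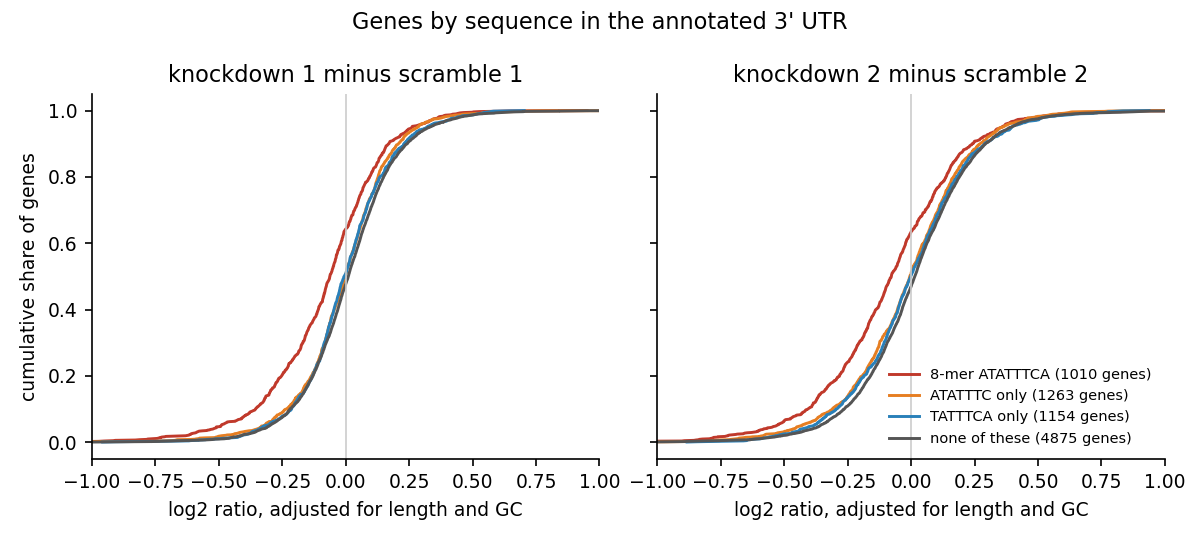
Cumulative share of genes against the log2 ratio of knockdown 1 to scramble 1 (left) and of knockdown 2 to scramble 2 (right), adjusted for exon length and for 3′ UTR length and GC content, for genes grouped by the sequence in their annotated 3′ UTR. Genes with the 8-mer ATATTTCA lie to the left in both pairs, with medians of −0.06 and −0.08 against 0.01 and 0.02 for genes without the sequence.

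Inflammatory cytokine and NF-kB genes were higher as a list, with 20 of 25 members above their scramble level and a median log2 fold change of 0.38 (camera adjusted p = 1.45e-06, and adjusted p = 0.956 with an estimated correlation). IL6, an inflammatory cytokine gene on chromosome 7, went from 65.2 ± 5.77 to 138 ± 4.81 CPM (mean ± SD, n = 2), a log2 fold change of 1.08 (SE 0.14). The neutrophil chemokine gene CXCL8 went from 231 ± 24.6 to 457 ± 61.7 CPM, PTGS2, which encodes cyclooxygenase 2, from 155 ± 28.0 to 262 ± 0.892 CPM, and CXCL1 from 59.0 ± 17.7 to 106 ± 14.7 CPM. No member passed edgeR's test over all genes, 10 had an unadjusted p under 0.05, and 4 were called by DESeq2. When adjusted over the list alone 10 passed: IL6, CXCL8, PTGS2, CXCL1, IL24, CXCL3, CSF2, CSF3 and CCL20 rose and IL11 fell. IL11 held an ATATTTC or TATTTCA heptamer in the 3′ UTR, as did CXCL1 and IL24 among those that rose. The regulators NFKBIA, NFKB1, NFKB2 and TNFAIP3 and the adhesion gene ICAM1 had log2 fold changes between −0.01 and 0.19 and did not pass. CXCL1 and CXCL3 have close paralogs that could share their reads. The list was not called by fry (adjusted p = 0.558). With 2 libraries per group, none of the 36 lists was called by fry or with an estimated correlation. The median of the cytokine list was 0.305 in knockdown 1 minus scramble 1 and 0.503 in knockdown 2 minus scramble 2. Without knockdown replicate 2 the median was 0.07 (camera adjusted p = 0.0262).

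Mammary basal and stem cell markers were lower as a list, with 16 of 20 members below their scramble level and a median log2 fold change of −0.16 (camera adjusted p = 0.00811, and adjusted p = 0.956 with an estimated correlation). The integrin genes ITGB4 (299 ± 20.6 to 186 ± 8.90 CPM) and ITGA6 (667 ± 62.7 to 443 ± 33.0 CPM, mean ± SD, n = 2) fell when adjusted over the list alone, with edgeR adjusted p of 0.0241 and 0.0353. Their products pair as a laminin receptor of basal cells. The low-abundance genes NGFR, ALDH1A3 and LGR5 had log2 fold changes of −1.36 (SE 0.53), −0.69 (SE 0.27) and −1.07 (SE 0.44) and did not pass, and PROCR, TP63 and SOX9 lay between −0.09 and 0.00. ITGA6 and 6 other members held an ATATTTC or TATTTCA heptamer in the 3′ UTR, and the 13 members without one had a median of −0.52. The call was also lost without scramble replicate 1 (adjusted p = 0.229) and without a filter on low counts (adjusted p = 0.161), and the median was −0.25 without knockdown replicate 1.

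The IGF axis genes did not shift together: 12 of 21 tested members had higher and 9 lower values, and the list was not called (camera adjusted p = 0.823). No member passed over all genes or adjusted over the list alone, 4 had an unadjusted p under 0.05 in edgeR, and DESeq2 called 0. The smallest p-values belonged to IGF2BP3 (40.7 ± 2.95 to 27.3 ± 1.93 CPM), the insulin receptor substrate gene IRS1 (166 ± 8.99 to 110 ± 24.8 CPM), STC1 (238 ± 7.47 to 315 ± 33.4 CPM) and IGF2, which was close to absent at 0.659 ± 0.313 and 1.74 ± 0.361 CPM (mean ± SD, n = 2). IGF1R stood at 154 ± 46.4 and 128 ± 40.8 CPM, and INSR at 36.8 ± 3.53 and 37.4 ± 3.46 CPM. IGFBP4, the most abundant binding protein gene of the list, stood at 1912 ± 103 and 2193 ± 312 CPM. PAPPA, PAPPA2, IGFBP1, IGFBP6, IGFBP7, IRS2, GRB10, ADAM12, IGF2BP2, IGF2R, LRP1, STC2, HTRA1 and TMEM219 had log2 fold changes from −0.59 for PAPPA to 0.42 for PAPPA2, each with an edgeR adjusted p above 0.9. Among the 9 members with an ATATTTC or TATTTCA heptamer in the 3′ UTR, IGF2BP3, IRS1, PAPPA and IGF1R lay lower. IGF2 and, slightly, INSR lay higher, and GRB10, ADAM12 and IRS2 held a heptamer as well. In the fit of genes without the heptamers, 9 of 12 members were higher, with a median of 0.14 (camera adjusted p = 0.243). FOXO and insulin feedback targets had 18 of 21 members above their scramble level, a median log2 fold change of 0.13 and a camera adjusted p of 0.0839. CITED2 lay at 0.27 (SE 0.14) and BNIP3, 1 of 12 members with an ATATTTC or TATTTCA heptamer, at −0.31 (SE 0.14). The FOXO list was called with an offset for exon length (camera adjusted p = 0.0339) or GC content (0.0383), both chosen after seeing the data. Without an offset its adjusted p was 0.956 with an estimated correlation and 0.722 by fry.

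**Figure D3:**
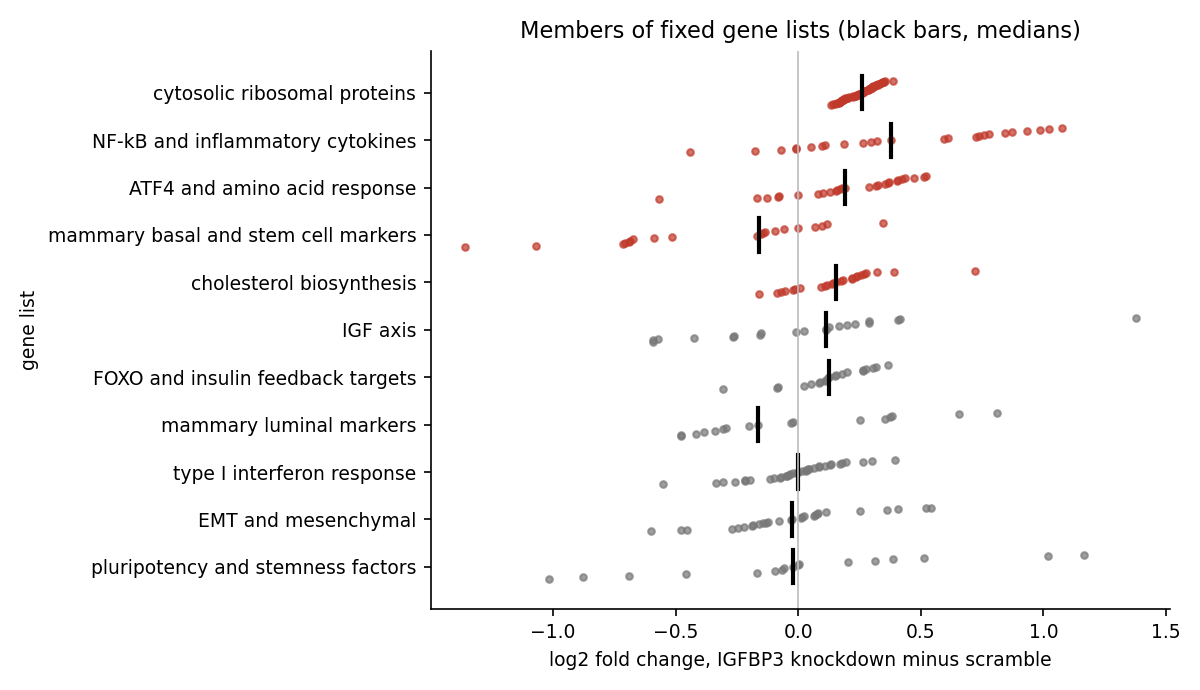
Log2 fold change of each tested member of 11 gene lists, knockdown minus scramble, with the median of each list as a black bar; red marks the 5 lists called by camera with a preset correlation. The medians run from −0.16 for the mammary basal and the mammary luminal markers to 0.38 for the inflammatory cytokine genes.

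All 59 cytosolic ribosomal protein genes had values above their scramble level, with a median log2 fold change of 0.26 (camera adjusted p = 1.45e-06, and adjusted p = 0.956 with an estimated correlation). That correlation was 0.977, so the 59 genes moved almost as 1. Between the scramble libraries the median difference of the list, replicate 2 minus 1, was 0.28, and between the knockdown libraries 0.50. None of the 59 passed edgeR's test over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2. The call was also lost without scramble replicate 1 (median 0.12, adjusted p = 0.238) and without knockdown replicate 2, where the median was −0.02 and the adjusted p 0.900. The median was 0.41 without scramble replicate 2 and 0.50 without knockdown replicate 1. Across 10247 expressed genes, which are not independent replicates, Spearman's rho of the log2 ratio with exon length was −0.33. The median was 0.11 in the 1025 shortest and −0.09 in the 1025 longest genes, and rho was −0.42 between the scramble and −0.49 between the knockdown libraries. With an offset for exon length, chosen after seeing the data, the ribosomal list kept 59 of 59 members higher, with a median of 0.20 (camera adjusted p = 3.66e-06).

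ATF4 and amino acid response genes were higher as a list, with 21 of 27 members above their scramble level and a median log2 fold change of 0.19 (camera adjusted p = 0.0073, and adjusted p = 0.956 with an estimated correlation). VEGFA (527 ± 33.3 to 698 ± 45.0 CPM), CEBPB (56.8 ± 6.65 to 76.9 ± 4.90 CPM) and SESN2 (13.1 ± 0.285 to 18.2 ± 0.221 CPM, mean ± SD, n = 2) had the smallest p-values on the higher side, while the amino acid transporter gene SLC7A5 lay lower, at 241 ± 36.2 and 163 ± 27.8 CPM. Cholesterol biosynthesis genes had 19 of 25 members above their scramble level and a median of 0.16 (camera adjusted p = 0.022, and adjusted p = 0.956 with an estimated correlation), with log2 fold changes of 0.39 (SE 0.15) for FDFT1 and 0.32 (SE 0.13) for FDPS. No member of either list passed edgeR's test over all genes or adjusted over the list alone, with 5 ATF4 and 3 cholesterol genes at an unadjusted p under 0.05 and 0 called by DESeq2. The ATF4 call was also lost without scramble replicate 1 (adjusted p = 0.229) or knockdown replicate 2 (median 0.08, adjusted p = 0.286) and without a filter on low counts (adjusted p = 0.0693), and the median was 0.30 without knockdown replicate 1. The cholesterol call was also lost without scramble replicate 2 (median 0.03, adjusted p = 0.824), knockdown replicate 1 (adjusted p = 0.233) or knockdown replicate 2 (adjusted p = 0.141), without a filter (adjusted p = 0.0738) and among genes without the heptamers, a set chosen after seeing the data (adjusted p = 0.0708). Without scramble replicate 1 the cholesterol median was 0.27.

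With all 4 libraries the other 30 lists tested were not called by camera, with adjusted p from 0.18 to 0.92 apart from the FOXO list. The medians of 23 of these 30 lists turned sign without 1 of the libraries, and those of the FOXO, epithelial junction, G2/M, p53, glycolysis, unfolded protein response and histone lists did not. In the lung metastasis signature of breast cancer, PTGS2 and CXCL1 rose adjusted over the list alone while the list had 10 of 19 members higher and a median of 0.03. Among matrix proteases and their inhibitors PLAU, the urokinase gene, fell adjusted over the list alone (426 ± 13.6 to 257 ± 11.2 CPM, mean ± SD, n = 2, edgeR adjusted p = 0.0193). PLAU held the 8-mer ATATTTCA. TIMP3, which held an ATATTTC or TATTTCA heptamer, had a log2 fold change of −0.53 (SE 0.14) that did not pass. Pluripotency and stemness factors went both ways, with KLF4 at 0.51 (SE 0.14) and ABCG2 at −1.02 (SE 0.34). Mammary luminal markers did too, with KRT18 at −0.42 (SE 0.14) and AREG at 0.65 (SE 0.23), and none of these passed. The EMT, TGF-beta, YAP, WNT, NOTCH, MAPK feedback, p53, hypoxia, glycolysis, oxidative phosphorylation, G1/S and G2/M lists had medians between −0.11 for TGF-beta and 0.10 for oxidative phosphorylation. TGF-beta was called lower without scramble replicate 2 (median −0.29, camera adjusted p = 0.031) and had a median of 0.13 without scramble replicate 1. Oxidative phosphorylation was called higher without scramble replicate 2 (adjusted p = 0.0114) or knockdown replicate 1 (median 0.27, adjusted p = 0.000145) and had a median of −0.10 without knockdown replicate 2. Medians lay between −0.03 and 0.17 for the epithelial junction, MYC, apoptosis, antigen presentation, fatty acid synthesis, unfolded protein response, NRF2, bone metastasis, histone and mitochondrially encoded lists. When 1 library was left out, the NRF2 median ran from −0.04 to 0.22 and that of antigen presentation from −0.03 to 0.23. Type I interferon genes had a median of −0.002 over 35 members. For the YAP, pluripotency, glycolysis, G1/S, bone metastasis and matrix protease lists the sign of the median and the direction of camera differed. With all 4 libraries, markers of other cell types were not called by camera. The 7 endothelial markers had a median of −0.04 and the 6 fibroblast markers of −0.21. The endothelial list was called lower without knockdown replicate 2 (median −0.52, adjusted p = 0.0262) and had a median of 0.27 without knockdown replicate 1. The fibroblast median was 0.32 without knockdown replicate 1, and −0.56 over 12 genes without a filter on low counts. The 4 blood cell markers tested, too few for a list test, summed to 9.95 CPM in the scramble and 6.98 CPM in the knockdown libraries, with CD14 and CSF1R lower and the scarcer PTPRC and CD68 higher. Genes of the mitochondrial chromosome took 4.85% of counts in both scramble libraries and 4.93% and 5.21% in the knockdown libraries.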

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

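The settings described in the methods as added, and all settings of the DESeq2 count, were chosen after seeing the data. The others were planned. The IGFBP3 transcript kept its direction in every setting that tested it, with a log2 fold change between −3.57 and −2.76 when 1 library was left out, and its call at an adjusted p under 0.05 in each but the GC offset (−3.12, adjusted p = 0.0792 in edgeR, against 2.12e-99 to 0.0469 elsewhere). It was not called at an adjusted p under 0.01 (adjusted p = 0.0453). The count of genes changed by IGFBP3 knockdown, 1 in edgeR, became 39 with DESeq2, 77 without a filter on low counts and 0 at an adjusted p under 0.01, with the GC offset or among genes without the heptamers (a set that leaves out IGFBP3). It ran from 1 to 42 when 1 library was left out. With the replicate block the count was 985, and 856 with the exon-length offset and the replicate block. The labels do not say that the numbers pair the libraries. Same-numbered libraries of the 2 groups were closer, with a chi-square per degree of freedom of 9.37 and 17.41, than libraries of one group (19.75 and 24.67). Libraries that differed in both group and number stood at 37.15 and 20.71. These values and the correlation of 0.49 between the deviations of same-numbered libraries go with a pairing that the main fit leaves out. They rest on 2 pairs, so the counts with the block stay a hint. Grouping the libraries by number instead of by treatment called 86 genes, 68 of them lower in the libraries numbered 2, which points to a structure of the samples. The remaining split called 0 in edgeR, with 53 genes at an unadjusted p under 0.05. DESeq2's count of 39 ran from 2 to 32 when 1 library was left out and was 170 with a replicate block, 60 with the exon-length offset (38 shared with the 39) and 14 among genes without the heptamers (12 shared). Of the 176 genes that the rule took over all lists, 1 was called by edgeR, 28 by DESeq2, 33 without a filter, 104 with the replicate block, 94 with the block and length offset, 0 with the GC offset or without the heptamer genes, and 1 to 13 when 1 library was left out. The count of 5 called lists was 2 without a filter, 2 to 6 when 1 library was left out, and 0 with an estimated correlation or with fry. The list cytosolic ribosomal proteins ran from an adjusted p of 2.23e-14 to 0.900 when 1 library was left out and turned to the lower side without knockdown replicate 2. Leaving out 1 library also leaves the numbers 1 and 2 uneven over the groups, so these shifts may hold the difference between the numbers. Within same-numbered libraries the medians of the 5 called lists kept their sign. For numbers 1 and 2 they were 0.305 and 0.503 for cytokine, 0.133 and 0.366 for ribosomal and 0.226 and 0.258 for ATF4 genes. They were 0.072 and 0.244 for cholesterol genes and −0.166 and −0.154 for basal markers. The cause of the changes between settings was not tested. Among single named genes, 26 values changed sign without passing a threshold in either fit and none did so as a called value. At this depth and spread edgeR recovered 10.4% of simulated 1.5-fold changes, so changes of that size would mostly be missed. The simulation drew genes independently and held no difference between the numbers 1 and 2. In the data edgeR did not call TNFSF18 at 3.36-fold (adjusted p = 0.3025) or NCEH1 at 2.54-fold (adjusted p = 0.245), so larger changes could be missed too.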

Other observations

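The tests of the fixed gene lists by camera and fry, and the list medians with a library left out, were planned. All other tests in this part, and the use of the planned values to weigh explanations, were chosen after the results were seen.

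Some called genes had neither ATATTTC nor TATTTCA in the 3′ UTR. Among 8500 tested genes of this kind DESeq2 called 14, while edgeR called 0. The lower ones were VIPR1, P2RY6, PRKCA, ITGB4, CST1 and DNAH2, and the higher ones HSD17B10, TNFSF18, JUND, IL6, NCEH1, CXCL8, AKIRIN1 and H2AX. PRKCA, which encodes protein kinase C alpha, went from 233 ± 15.1 to 146 ± 19.9 CPM, and VIPR1, a neuropeptide receptor gene, from 40.4 ± 16.7 to 19.2 ± 4.21 CPM (mean ± SD, n = 2). VIPR1 and P2RY6 were not among the 39 genes called over all genes, and the other 12 were. Of 1926 GO sets in the deposited annotation, camera called 1, cytoplasmic translation, with 134 of 157 genes higher and a median log2 fold change of 0.22 (adjusted p = 0.00451 in limma, and 1 with an estimated correlation). Its adjusted p was 0.122 after the exon-length offset, and 0 of 311 KEGG sets were called.

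Genes with ATATTTC in the 3′ UTR were lower in the knockdown libraries, with an effect of −0.075 on the log2 scale over 2273 genes and a z of −13.88, where the next heptamer outside the 8-mer ATATTTCA reached −4.81. Base composition or length of the 3′ UTR is argued against, since 87 control heptamers with the same bases in another order went no lower than −2.48. Heptamers sharing a run of bases with the 8-mer were set aside from these controls, among them TATTTCA, which reached −12.07. A candidate explanation is seed pairing of the RNA used to silence IGFBP3. ATATTTC had the lowest z of all heptamers in knockdown 1 minus scramble 1 (−12.95) and in knockdown 2 minus scramble 2 (−11.23). It was chosen on the mean of these 2 contrasts, so the ranks largely restate the choice. IGFBP3 holds ATATTTC without the last A of the 8-mer. The 1263 genes with ATATTTC but not the 8-mer had an adjusted median of −0.004. The median was −0.061 with the 8-mer and 0.014 for genes without its inner hexamer. An endogenous microRNA with this seed cannot be told apart from the silencing RNA. The reason is that 13.2% of heptamers occur in the IGFBP3 transcript and the silencing sequences are not given. Under seed pairing of the silencing RNA, falls of genes such as STX2 and NEK7 may not follow from the loss of IGFBP3 protein, while under a microRNA that responds to this loss they would.

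Inflammatory cytokine genes, IL6 and CXCL8 foremost, were called higher as a list by camera. No list was called with an estimated correlation or by fry (smallest adjusted p 0.956 and 0.558), so these tests do not set this list apart. The median went from 0.38 to 0.07 without knockdown replicate 2. It was 0.305 in knockdown 1 minus scramble 1 and 0.503 in knockdown 2 minus scramble 2. Blood cells in the knockdown cultures stay open, since the 4 markers tested were scarce and went both ways: they summed to 6.98 CPM there and 9.95 CPM in the scramble libraries, with CD14 and CSF1R lower and PTPRC and CD68 higher. A type I interferon response to double-stranded RNA is argued against by the median of −0.002 of its list against 0.38 for the cytokines, a gap that was smaller without knockdown replicate 2 (−0.05 against 0.07). Relief from the seed of the scramble RNA at sites in these transcripts is argued against, as 0 of the 9 members that rose held GTCGCCC or TCGCCCA in the 3′ UTR. Loss of IGFBP3 itself and indirect effects of other silenced genes both stay open and were not tested, since the design holds no rescue.

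Genes with GTCGCCC in the 3′ UTR were higher in the knockdown libraries, with an effect of 0.08 over 471 genes and the highest z of the scan, 7.98. Over all 4 libraries composition is argued against by 87 heptamers of the same bases that went no higher than 3.31. Those sharing a run of bases with the 8-mer GTCGCCCA were set aside here too. This control does not cover a longer sequence shared by these 3′ UTRs. Heptamers that are not part of the 8-mer GTCGCCCA also ranked high: TGTCGCC (z 4.90), AAGCGAT (4.82), AGTCGCA (4.61) and GCGATTC (4.51). Between the knockdown libraries their z was 3.30, 3.08, −0.53 and 4.26. Whether a longer shared sequence accounts for part of the pattern was not tested and stays open. Seed pairing of the scramble RNA, which would lower these genes in the scramble libraries, is a candidate explanation. GTCGCCC had the highest z in knockdown 1 minus scramble 1 (6.30) and in knockdown 2 minus scramble 2 (7.41). It was chosen on the mean of these 2 contrasts, so the ranks largely restate the choice. The 332 genes with the 8-mer GTCGCCCA had an adjusted median of 0.061. The median was 0.064 for the 139 with GTCGCCC but not the 8-mer and 0.038 for the 200 with TCGCCCA only. In knockdown 1 minus scramble 2 the z of GTCGCCC was 2.99, below the highest of the 87 heptamers (3.30). Between the knockdown libraries it was 3.58 against 3.53, so the pattern is less even over the libraries than that of ATATTTC. No biological explanation was tested, and of the 13 genes called higher by DESeq2 only HSD17B10 held the heptamer.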
